A study of Homo sapiens with 48 samples.

How the data were processed

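RNA-seq of MCF7 and T47D cells given E2, FULV or DMSO for 45 min or 4 h was deposited as 48 samples, 4 in each of 12 groups. The labels number the samples of a group as replicates without saying whether they were separate cultures, so the p-values measure only the spread between these samples. Per the labels' protocols, libraries were poly(A)-selected and strand-specific, RNA had an integrity number above 7, and sequencing was single-end on a NovaSeq instrument with more than 20000000 reads per sample. Per the submitters' processing notes, the genome build was hg38. The aligner, the counting tool, the annotation and the statistical test are not given in the sources used here.

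The study's 8 tables each held 1 comparison of E2 or FULV with DMSO in 1 line at 1 time, with a row of statistics per gene and 0 columns of values per sample. The tables' names say that no filter was applied, and 31618 to 32853 genes were listed in each. The abundance column was in counts per 1000000 (CPM), as the authors computed it, with 1 value per gene rounded to 0.1. This unit was inferred from the deposited values. The column summed to between 999905.9 and 999915.6 in each table, and the implied standard error fell with abundance at a slope between -0.5 and -0.45 on log scales while its slope on gene length lay between -0.0089 and 0.0047. The abundances in the E2 and FULV tables of the same line and time were identical, and the sources do not say which samples they average. In the E2 table of T47D at 45 min, for example, all 40 genes with a log2 fold change below -4 were listed above 0 and all 52 above 4 were listed at 0, which an average over the DMSO samples would give. The deposited fold changes are log2 values of the treated group relative to DMSO, as the authors gave them, rounded to 0.01. The authors' p-values and adjusted p-values were deposited as log10 values. Their adjusted p-values equalled a Benjamini-Hochberg adjustment over all genes of the table within 0.0099 on the log10 scale. Where the authors' p was too small to be stored, it was set here to a log10 of -308. Depth per sample could not be read from the tables. In place of it, the median implied standard error by abundance was used as precision, and it lay between 0.31 and 0.37 for genes of 1 to 2 CPM, between 0.099 and 0.12 for 10 to 20 CPM and between 0.041 and 0.068 for 100 to 200 CPM.

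Each gene's z was computed from the authors' two-sided p and the sign of the log2 fold change, and its implied standard error was the absolute fold change divided by the absolute z. Where the absolute log2 fold change was below 0.05 or p above 0.9, the median over the 201 genes nearest in abundance was used, since rounding would dominate. Genes were called at an authors' adjusted p below 0.05. The one entry per table that was not a gene, the sequencing control phiX174 with an abundance of 0, was left out. Gene positions came from GENCODE 29, which matched 92.9% to 93.1% of the identifiers per table. Between 75% and 75.5% of the genes of a table had a symbol. Where a gene was listed at 0 CPM, no fold change is given.

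The groups, comparisons, tests, gene lists, alternatives and rule for named genes were chosen before the data were examined, except where the closing parts say otherwise. The rule named in each comparison the 6 genes with the largest positive and the 6 with the largest negative log2 fold change among the 200 called genes with the smallest p-values, leaving out genes without a symbol. In every comparison it also named ESR1, GREB1, TFF1, PGR, MYC, CCND1, CXCL12, PDZK1 and RET, and up to 4 members with the smallest p-values of each list described. For differences between comparisons it named the 5 genes with the largest positive and the 5 with the largest negative z.

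The 22 gene lists, with 451 entries and 417 distinct genes, held oestrogen-induced genes, oestrogen-repressed genes, immediate early genes, G1/S and replication genes, G2/M genes, ribosome biogenesis, endoplasmic reticulum stress, cholesterol synthesis, the BCL2 family, p53 targets, luminal identity, basal identity, cofactors of the oestrogen receptor, aryl hydrocarbon receptor targets, interferon response, heat shock, hypoxia and glycolysis, TGF-beta and BMP signalling, growth factor signalling, mitochondrial messenger RNAs, reference genes and markers of other cell types. Some genes stood in more than 1 list, so the lists are not independent. The oestrogen-induced list, for example, shared MYC with the immediate early list, RARA with the cofactors and TIPARP with the aryl hydrocarbon receptor targets. Each list was compared with all other genes by cameraPR of limma 3.58.1 in R 4.3.3 on the z values, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 22 lists. A correlation could not be estimated without values per sample, so no call is known to hold with an estimated correlation, and 0.05 was tried instead.

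Differences between fold changes, 12 in all, were tested per gene by a two-sided z of the difference over the root of the summed squared implied standard errors, with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons of the 2 lines or the 2 times share no samples. Those of E2 with FULV share the DMSO samples, which makes the sum of squares too large. The relation of E2 and FULV fold changes was set against 1000 simulated draws in which FULV had no effect. In them the shared samples gave each gene a covariance of 0.5 of the geometric mean variance of its fold changes. Where the standard errors with E2 and FULV differ, shared samples cannot make up 0.5 of both variances. The simulated slope may then be too high. Over all genes the draws held no E2 effect either. Over genes called with E2 they kept the E2 fold changes, and the simulation shrank the E2 effects according to the tail of their z values, with exponents of 3.2, 2.47, 2.45 and 2.7 for MCF7 at 45 min and 4 h and T47D at 45 min and 4 h. It was revised after first slopes had been seen, and it treats genes as independent. Overlaps of called genes were set beside the number for independent lists of the same sizes.

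The steps were tested on simulated data. Of 200 genes changed between lines, 58% with a difference of 0.5 and 86% with a difference of 1.0 in log2 were recovered with the right sign, and 11 unchanged genes were called, 7.1% of the calls. The implied standard error had a median ratio of 1 to the true one over 15039 genes. The simulated p-values were made from a normal z, so this checks only the arithmetic and the rounding. Whether the authors' p-values follow a normal z was not tested, and the implied standard errors and the tests of differences rest on it. In 20 simulated studies without a FULV effect, the slope over genes at or above the median abundance lay more than 2 standard deviations from the expected one in 0 studies built on T47D at 45 min and 3 built on T47D at 4 h, with a mean deviation of 0.46 and 0.90 standard deviations. Over called genes of any abundance the mean deviation was 1.69 and 6.51, so slopes of that kind were not relied on. Over genes at or above the median abundance, a true slope of -0.1 was found in 20 of 20 studies built on each time. Over called genes of any abundance it was missed, with mean deviations of 1.26 and 4.72 standard deviations in the wrong direction. These studies were drawn with the covariance share, the normal errors and the independent genes that the simulation itself assumes, so they do not check those assumptions. A list shifted by 1.0 was recovered by cameraPR, and 2 of 100 unshifted lists had a p below 0.05.

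The alternatives tried were a threshold of 0.01, a minimum absolute log2 fold change of 1 (0.5 for the difference between E2 and FULV), an own adjustment over all genes, only genes in all 8 tables (24190 genes), only genes at or above the median abundance, an inter-gene correlation of 0.05, ranks, the log2 fold change in place of z, and a covariance of 0.5 of the geometric mean variance for differences that share DMSO. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used. No new model was fitted to samples, no direction per sample could be counted, and no sample could be left out or moved between groups, because the tables hold no values per sample.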

Results

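Gene expression was measured by RNA-seq in 2 human breast cancer cell lines, MCF7 and T47D, both of which carry oestrogen receptor alpha and divide in response to oestrogen. The cells received oestradiol (E2, the main natural oestrogen), fulvestrant (FULV, an antagonist that blocks the oestrogen receptor and promotes its degradation) or the solvent DMSO. RNA was taken after 45 min or 4 h. Each of the 12 combinations of line, treatment and time had 4 samples, 48 in all. The series title places the study in work on how fulvestrant acts on chromatin bound by the receptor, and the 8 comparisons of a treatment with its solvent address what each ligand did to RNA levels early and later. Doses and culture conditions were not given in the sources used here. The labels' protocol states more than 20000000 reads per sample. The exact depth of each sample is unknown, because the tables used here hold the authors' statistics per gene and no value per sample, so no interval or detection limit was computed from counts. A gene was called changed where the authors' adjusted p lay below 0.05. Each error given below is a standard error (SE) implied by the authors' fold change and p-value, and "at most" marks genes whose p-value was too small to be stored. The RNA levels given are the authors' abundances in counts per 1000000 (CPM), 1 value per gene for each line and time, and which samples they average is not given in the sources used here.

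At 45 min of E2, MCF7 cells held more RNA of several regulators. The authors' deposited table gave MYC, a transcription factor that drives growth, a log2 fold change of 2.17 (SE at most 0.058) at an abundance of 84.3 CPM. The forkhead factor gene FOXC1 rose by 2.88, the TGF-beta binding protein gene VASN by 1.94, SOCS3, a feedback inhibitor of cytokine signalling, by 1.82 and the antiproliferative gene TOB1 by 1.34 in the authors' deposited table. CCND1, which encodes cyclin D1, rose by 0.67 (SE 0.033, adjusted p = 2.04e-88) and the chemokine gene CXCL12 by 0.38 (SE 0.06, adjusted p = 1.23e-07) in the same table of the authors. Among the strongest decreases in the authors' deposited table, TNFRSF11B, the decoy receptor osteoprotegerin, had a log2 fold change of -0.86, the pseudokinase gene TRIB1 -0.78, the endothelin precursor gene EDN1 -0.74, the polo-like kinase gene PLK2 -0.60 and the histone gene H2BC6 -0.93. In all, 355 of 32028 tested genes were called (1.11%), 272 higher and 83 lower, by the authors' deposited table.

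Of the list of oestrogen-induced genes fixed beforehand, 21 of 42 members rose and 0 fell in MCF7 at 45 min, or 27 and 1 adjusted over the list alone, where 1.11% of all genes were called. The median log2 fold change of the list was 0.42 and limma's cameraPR gave an adjusted p of 8.61e-167. With the log2 fold change in place of z as the measure of each gene, this list was not called (adjusted p = 0.132). In that setting the only list calls left in the 8 comparisons were of the oestrogen-induced list at 4 h of E2 in both lines and of ribosome biogenesis at 4 h of E2 in MCF7. The authors' deposited table gave XBP1, a regulator of the secretory pathway, 1.00 (SE 0.038), STC2, a stanniocalcin hormone gene, 1.18 (SE 0.056) and FOS 1.46 (SE 0.069). TFF1, which encodes a secreted trefoil peptide, rose by 0.28 (SE 0.053, adjusted p = 3.89e-05) in the authors' deposited table. In contrast, GREB1 at -0.03 (SE 0.04, adjusted p = 0.977), PGR at 0.30 (SE 0.19, adjusted p = 0.891) and RET at 0.20 (SE 0.068, adjusted p = 0.174) were not called in the authors' deposited table. Nor were PDZK1 at 1.07 (SE 0.77, adjusted p = 0.977) and ESR1 at -0.03 (SE 0.041, adjusted p = 0.977) in that table of the authors. Of the 30 immediate early genes, 9 rose and 4 fell (10 and 7 adjusted over the list alone, adjusted p = 1.26e-50 with cameraPR). GADD45B at 1.08 and KLF10 at 1.27 were among the members that rose in the authors' deposited table. On ranks, the immediate early list was not called (adjusted p = 0.595). Of 9 targets of the aryl hydrocarbon receptor, 3 rose and 0 fell, over all genes and also adjusted over the list alone (adjusted p = 3.21e-15 with cameraPR). They were TIPARP at 1.49, the amino acid transporter gene SLC7A5 at 0.41 and CYP1B1, which encodes an oestrogen-hydroxylating enzyme, at 0.37 in the authors' deposited table. TIPARP also stood in the oestrogen-induced list. The p of this list on ranks was 0.125.

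After 4 h of E2, MCF7 cells showed the widest response of the 8 comparisons, with 4904 of 32170 genes called (15.2%), 2762 higher and 2142 lower, by the authors' deposited table. GREB1, a coregulator of the oestrogen receptor at chromosome 2, 11482341 to 11642788 (hg38), rose by 3.01 (SE at most 0.08) at an abundance of 203.8 CPM in that table of the authors. The progesterone receptor gene PGR, at chromosome 11, 101029624 to 101130524, rose by 3.36 (SE 0.11) at an abundance of 3.8 CPM in the authors' deposited table. The largest increases of the named set were of ADORA1, an adenosine receptor gene, at 5.22 (SE 0.24) and SCNN1G, a subunit of the epithelial sodium channel, at 4.78 (SE 0.18) in the authors' deposited table. They were followed by the complement receptor gene C5AR2 at 4.06, the prostaglandin E synthase gene PTGES at 4.02, the adrenoceptor gene ADRA2A at 3.74 and the neuropeptide Y receptor gene NPY1R at 3.53 in the authors' deposited table. RET, a receptor tyrosine kinase, rose by 1.98, CXCL12 by 1.99, MYC by 1.88, CCND1 by 1.86, TFF1 by 1.11 and PDZK1 by 2.70 (SE 0.56, adjusted p = 2.34e-05) in the authors' deposited table. ESR1, the gene of the receptor itself, had a log2 fold change of -0.18 (SE 0.032, adjusted p = 2.29e-07) in the authors' deposited table. The strongest decreases named were TGFB3 at -1.66, the interleukin 1 receptor gene IL1R1 at -1.63, the pro-apoptotic gene BMF at -1.34, WNT2B at -1.28, the epithelial transcription factor gene GRHL3 at -1.21 and SALL4 at -1.20 in the authors' deposited table.

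Of the oestrogen-induced list, 41 of 42 members rose in MCF7 at 4 h and 0 fell, also when adjusted over the list alone, with a median of 1.92. The p of cameraPR was too small to be stored, and with an inter-gene correlation of 0.05 the adjusted p was 6.24e-169. CA12, a carbonic anhydrase gene, at 1.62 and the cadherin gene CELSR2 at 1.18 were among the members in the authors' deposited table. Of 19 oestrogen-repressed genes, 15 fell and 0 rose (17 and 1 adjusted over the list alone, median -0.77, adjusted p = 8.10e-33 with cameraPR, 0.329 on the log2 fold change). They included CYP1A1, a xenobiotic-metabolising enzyme, at -1.09 and TP53INP1, a p53 target, at -1.13 in the authors' deposited table. All 31 ribosome biogenesis genes rose, with and without adjustment over the list alone, with a median of 0.89 (adjusted p = 1.70e-117 with cameraPR). The nucleolar genes DDX21 at 1.12, MYBBP1A at 1.09, NOLC1 at 1.07 and DKC1 at 1.05 had the smallest p-values of that list in the authors' deposited table. Of 31 genes of the G1/S transition and DNA replication, 19 rose and 0 fell (23 and 0 adjusted over the list alone, median 0.29, adjusted p = 9.24e-10 with cameraPR). The replicative helicase genes MCM2 at 0.57 and MCM6 at 0.53, the licensing factor gene CDT1 at 0.72 and the phosphatase gene CDC25A at 1.15 were the named members in the authors' deposited table. Of 14 genes of TGF-beta and BMP signalling, 9 fell and 1 rose (9 and 3 adjusted over the list alone, median -0.51, adjusted p = 1.16e-08 with cameraPR), with BMP7 at -0.51, ID3 at -0.57 and TGFB2 at -0.53 in the authors' deposited table.

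Apoptosis and p53 genes moved both ways in MCF7 at 4 h. Of 15 BCL2 family genes, 6 fell and 3 rose (6 and 4 adjusted over the list alone, median -0.12, adjusted p = 1.04e-03 with cameraPR, 0.297 on ranks). The pro-apoptotic BAK1 fell by 1.07 and the anti-apoptotic BCL2 rose by 0.68, while BCL2L11, which encodes the pro-apoptotic protein BIM, rose by 0.28 in the authors' deposited table. Of 20 p53 targets, 8 fell and 2 rose (9 and 3 adjusted over the list alone, median -0.12, adjusted p = 0.007 with cameraPR), with BTG2 at -0.80, MDM2 at 0.77 and AEN at 0.95 in the authors' deposited table. Growth factor signalling genes rose in 10 and fell in 5 of 21 cases (10 and 6 adjusted over the list alone, median 0.08, adjusted p = 9.98e-11 with cameraPR, 0.273 on ranks). Its leading members in the authors' deposited table were IGFBP4, an IGF binding protein, at 2.79, IRS1 at 0.73 and the IGF1 receptor gene IGF1R at 0.57. Endoplasmic reticulum stress genes rose in 8 and fell in 2 of 18 cases (9 and 3 adjusted over the list alone, adjusted p = 2.69e-05 with cameraPR, 0.056 on ranks), with DNAJB9 at 1.05 and the chaperone gene HSPA5 at 0.33 in the authors' deposited table. Of 10 heat shock genes, 6 rose and 3 fell, also adjusted over the list alone (adjusted p = 2.49e-04 with cameraPR, 0.148 on ranks).

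Genes of the immunoglobulin heavy chain constant region, which belong to antibody-producing B cells, were called higher with E2 in MCF7. They were singled out after their values were seen, although IGHG1 to IGHG4 at 45 min met the rule for named genes. At 45 min IGHG1 to IGHG4 were called (adjusted p between 8.13e-06 and 1.51e-04 in the authors' deposited table), each listed at 0 CPM, so no fold change is given. At 4 h, 9 of 11 listed constant genes were called and 6 of these were listed at 0. The other 3 in the authors' deposited table, each at 0.2 CPM, were IGHG1 at 5.38 (SE 0.98), IGHE at 4.55 (SE 0.71) and IGHA1 at 2.78 (SE 0.63). The called genes span chromosome 14 from 105583731 to 105771405 (hg38). IGHM and IGHD, the next constant genes, were not called (adjusted p = 0.708 and 0.933 in the authors' deposited table). Of the 2 heavy chain variable and 2 light chain genes listed at 4 h, 0 were called by the authors' adjusted p and 0 had an unadjusted p below 0.05. In T47D at 4 h, IGHG4 alone was called, again listed at 0 (adjusted p = 0.032 in the authors' deposited table). With FULV 0 constant genes were called in either line by the authors' adjusted p, and 1 had an unadjusted p below 0.05, in MCF7 at 45 min. The IGHG genes are close copies of each other, so the split of reads among them is uncertain.

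**Figure D1:**
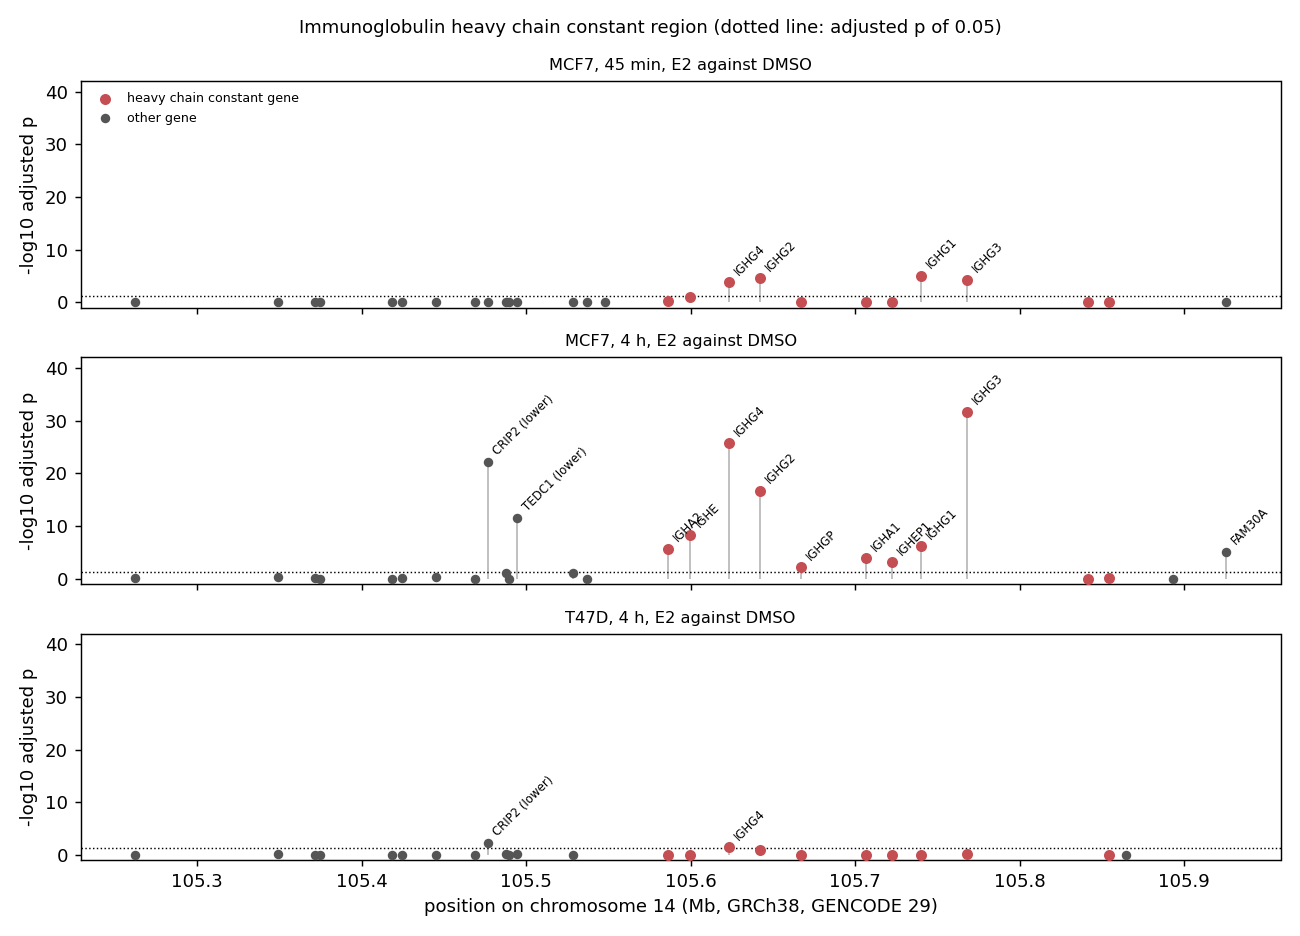
The negative log10 of the authors' adjusted p with E2 against DMSO (vertical, dotted line at 0.05) by position on chromosome 14 (horizontal, Mb, hg38) around the immunoglobulin heavy chain constant region, in panels for MCF7 at 45 min, MCF7 at 4 h and T47D at 4 h, with constant genes in red, other genes in grey and "lower" beside called genes that fell. At 4 h in MCF7, 9 of the 11 constant genes listed lie above the line, where 15.2% of all genes were called. Of the other genes shown, FAM30A, CRIP2 and TEDC1 do as well, while others such as TMEM121, CRIP1, MTA1, PACS2 and BRF1 do not.

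T47D cells responded to 45 min of E2 with 202 of 32181 genes called (0.628%), 166 higher and 36 lower, by the authors' deposited table. MYC, at chromosome 8, 127735434 to 127741434, rose by 2.92 (SE at most 0.078) at an abundance of 19.6 CPM in that table of the authors. SOCS3 rose by 3.58 (SE 0.14), ARC, an activity-regulated gene, by 3.77 (SE 0.18), RNF223 by 3.04 (SE 0.087) and the early response factor gene EGR3 by 3.76 (SE 0.39) in the authors' deposited table. H2BC3, also named by the rule, was called at an abundance listed at 0 (adjusted p = 0.039). The strongest decreases in the authors' deposited table were those of DDIT4, an inhibitor of mTOR signalling, at -0.75 (SE 0.067), JUNB at -0.71, the BMP target ID1 at -0.67, the homeobox gene DLX2 at -0.57, ZC3H12A at -0.55 and the kinase gene NUAK2 at -0.55. CXCL12 rose by 0.31 (SE 0.036, adjusted p = 7.24e-15) and CCND1 by 0.38 (SE 0.034, adjusted p = 2.24e-26) in the authors' deposited table. GREB1 at 0.07 (SE 0.05, adjusted p = 1.000), PGR at 0.04 (SE 0.032, adjusted p = 1.000), TFF1 at 0.48 (SE 0.17, adjusted p = 0.437), RET at 0.14, PDZK1 at 0.38 and ESR1 at -0.02 were not called in the authors' deposited table.

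Of the oestrogen-induced list, 16 of 42 members rose in T47D at 45 min and 0 fell (22 and 0 adjusted over the list alone, median 0.21, adjusted p = 5.06e-133 with cameraPR), where 0.628% of all genes were called. They included RARA, the retinoic acid receptor alpha gene, at 0.79, SIAH2, a ubiquitin ligase gene, at 0.82 and TIPARP at 1.18 in the authors' deposited table. Of 30 immediate early genes, 12 rose and 3 fell (14 and 4 adjusted over the list alone, median 0.33, adjusted p = 6.27e-70 with cameraPR), with FOS at 2.54 (SE 0.16), GADD45B at 1.44 and KLF6 at 0.56 in the authors' deposited table. Of 21 luminal identity genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone, adjusted p = 1.22e-25 with cameraPR). The epithelial factor gene ELF3 rose by 1.43 and TFAP2C by 0.92, and the pioneer factor gene FOXA1 had a log2 fold change of -0.23 in the authors' deposited table. In the TGF-beta and BMP list 4 genes fell and 1 of 14 rose, also adjusted over the list alone (adjusted p = 9.74e-06 with cameraPR, 0.284 on ranks). The members that fell included ID1, ID2 at -0.50 and ID3 at -0.40 in the authors' deposited table. Genes named as oestrogen-repressed went both ways, with 2 of 19 higher and 3 lower, also adjusted over the list alone. Their median was -0.01 and their mean 0.06, and cameraPR gave a shift upward (adjusted p = 3.56e-10) that turned to a shift downward and was not called on ranks (adjusted p = 0.818). The members that rose were the transcriptional repressor genes HES1 at 1.32 and BCL6 at 0.92 in the authors' deposited table.

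After 4 h of E2, T47D cells had 2766 of 31818 genes called (8.69%), 1576 higher and 1190 lower, by the authors' deposited table. GREB1 rose by 2.02 (SE at most 0.054) at an abundance of 122.8 CPM, CXCL12 by 1.39 (SE at most 0.037) at an abundance of 170.1 CPM and RET by 2.19 (SE 0.12) at an abundance of 6.1 CPM in that table of the authors. MYC rose by 1.90, PGR by 0.87 at an abundance of 852.4 CPM, CCND1 by 0.82, PDZK1 by 2.04 and TFF1 by 0.93 (SE 0.18, adjusted p = 5.75e-06), while ESR1 at 0.05 (SE 0.032, adjusted p = 0.550) was not called in the authors' deposited table. The largest increases named were the long non-coding RNA LINC01016 at 4.87 (SE 0.32), EGR3 at 4.82 (SE 0.37) and the lipid-binding protein gene SEC14L2 at 4.40 (SE at most 0.12) in the authors' deposited table. The next were PLCL1 at 3.39, GJA1, which encodes the gap junction protein connexin 43, at 3.33 and TMEM121B at 3.13 in the authors' deposited table. The largest decreases named were the adhesion genes AMIGO2 at -1.58 (SE 0.064) and CDH10 at -1.41, IL1R1 at -1.35, ENC1 at -1.28, the transcription factor gene SOX9 at -1.26 and FAM83A at -1.15 in the authors' deposited table.

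Of the oestrogen-induced list, 39 of 42 members rose in T47D at 4 h and 0 fell (40 and 0 adjusted over the list alone) with a median of 1.04. The p of cameraPR was too small to be stored, and it was 6.29e-167 after adjustment with a correlation of 0.05. STC2 at 2.57 and the formin gene FMN1 at 1.57 were among them in the authors' deposited table. Of 19 oestrogen-repressed genes, 13 fell and 1 rose (13 and 2 adjusted over the list alone, median -0.47, adjusted p = 7.54e-21 with cameraPR), with the receptor tyrosine kinase gene ERBB2 at -0.39, EFNA1 at -0.67 and TGFB3 at -0.54 in the authors' deposited table. Ribosome biogenesis genes rose in 30 of 31 cases, also adjusted over the list alone, with a median of 0.44 (adjusted p = 8.55e-63 with cameraPR, 0.577 on the log2 fold change). NOP56 at 0.65, DDX21 at 0.68 and RRP12 at 0.50 had the smallest p-values with NOLC1 in the authors' deposited table. Of 31 G1/S and replication genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.13, adjusted p = 1.24e-04 with cameraPR), with CDC6 at 0.50, E2F1 at 0.34 and UHRF1 at 0.44 in the authors' deposited table. Of 14 TGF-beta and BMP genes, 8 fell and 0 rose (9 and 0 adjusted over the list alone, median -0.45, adjusted p = 3.34e-17 with cameraPR), with ID2 at -0.93, BMP4 at -0.73 and the inhibin gene INHBB at -0.54 in the authors' deposited table. Of 10 heat shock genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.21, adjusted p = 7.27e-20 with cameraPR), led by BAG3 at 0.89 and HSPA8 at 0.64 in the authors' deposited table. Endoplasmic reticulum stress genes rose in 6 and fell in 2 of 18 cases (8 and 2 adjusted over the list alone, adjusted p = 5.03e-05 with cameraPR), with ATF4 at 0.33 in the authors' deposited table. Growth factor signalling genes rose in 8 and fell in 4 of 21 cases (8 and 6 adjusted over the list alone, adjusted p = 1.70e-05 with cameraPR, 0.770 on ranks), with IGFBP4 at 1.45 and ERBB3 at -0.43 in the authors' deposited table.

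**Figure D2:**
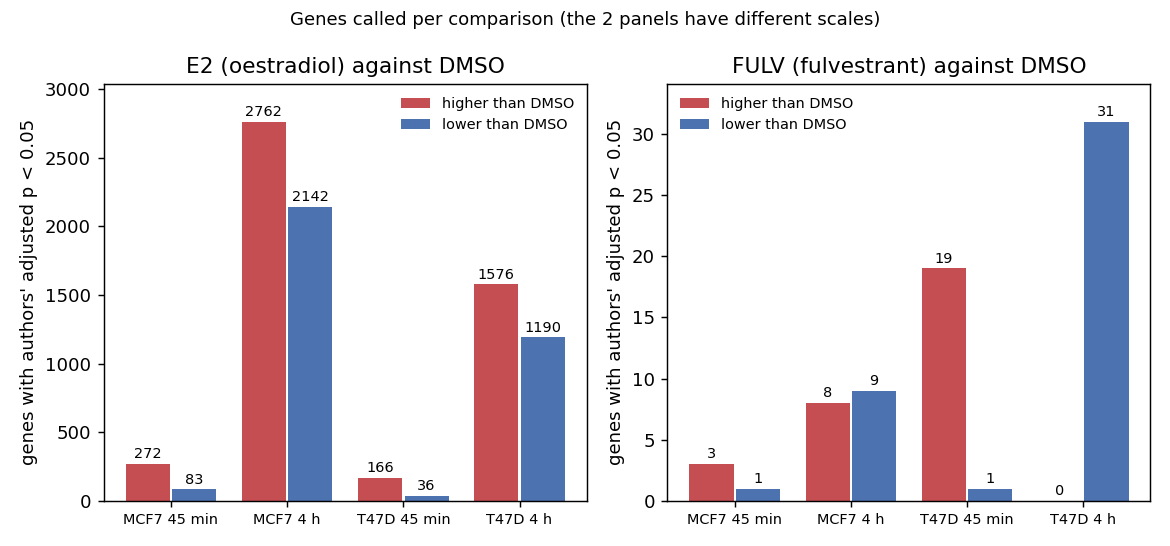
Number of genes called higher and lower in each of the 8 comparisons with DMSO at an authors' adjusted p below 0.05, with E2 and FULV in panels of different scales. E2 at 4 h called 4904 genes in MCF7 and 2766 in T47D, and FULV called between 4 and 31.

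FULV changed few genes at 45 min in MCF7. The authors' deposited table held 4 called genes of 31963 (0.0125%), with 3 higher and 1 lower. Of these 4, 3 were also called with E2 in the same direction, 2 higher and 1 lower, where independent lists would share 0.0272 and 0.00277. Both treatments were compared with the same DMSO samples, so for these 3 an effect of FULV cannot be told apart from chance in those samples. IGF2, an insulin-like growth factor gene, rose by 1.85 (SE 0.36, adjusted p = 0.006) at an abundance of 0.8 CPM, the early response factor gene EGR1 by 0.25 (SE 0.052, adjusted p = 0.019) and TOB1 by 0.18 (SE 0.039, adjusted p = 0.030) in the authors' deposited table. The gene that fell carried no symbol. None of the 9 fixed genes was called, or had an unadjusted p below 0.05, with MYC at -0.04 (SE 0.06), GREB1 at -0.09 (SE 0.051) and ESR1 at -0.05 (SE 0.046) in the authors' deposited table. Of the 30 immediate early genes 1 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.09, adjusted p = 5.44e-04 with cameraPR, 0.079 on ranks). This list also shifted upward with E2, compared with the same DMSO samples (adjusted p = 1.26e-50 with cameraPR). The ribosome biogenesis list, with a median of -0.06 (adjusted p = 2.47e-04), and the G1/S list, with a median of -0.06 (adjusted p = 9.73e-04), shifted downward by cameraPR with 0 members called and 0 adjusted over the list alone. At an unadjusted p below 0.05 in the authors' deposited table stood 0 and 3 of their 31 members each. With E2, compared with the same DMSO samples, the ribosome biogenesis list had a median of -0.04 (adjusted p = 0.053 with cameraPR) and the G1/S list of -0.07 (adjusted p = 1.06e-04). An effect of FULV on these 2 lists therefore cannot be told apart from the shared samples. Of 17 listed markers of other cell types (stromal, blood and endothelial genes) 0 were called, or 1 adjusted over the list alone and 4 at an unadjusted p below 0.05. The list shifted upward with a median of 0.40 (adjusted p = 0.038 with cameraPR, 0.154 with a correlation of 0.05). Among these, COL3A1 stood at 2.10 (SE 0.53, adjusted p = 0.324) at an abundance of 3.5 CPM in the authors' deposited table.

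At 4 h FULV called 17 of 32853 genes in MCF7 (0.0517%), 8 higher and 9 lower, by the authors' deposited table. STC2 had a log2 fold change of -0.38 (SE 0.071, adjusted p = 7.76e-04), GREB1 of -0.17 (SE 0.035, adjusted p = 0.005), WNT2B of -0.32 (SE 0.043, adjusted p = 5.62e-09) and RASGRP1 of -1.04 (SE 0.22, adjusted p = 0.006) in the authors' deposited table. C6orf141 at -0.32, the lipid phosphatase gene INPP4B at -0.22, EPS15L1 at -0.19, MED13L at -0.15 and ELP2 at -0.11 also fell in the authors' deposited table. The genes that rose were LAT2 at 2.36 (SE 0.55) at an abundance of 0.2 CPM, the kinase gene FRK at 0.49 (SE 0.088, adjusted p = 2.45e-04), the potassium channel gene KCNN4 at 0.37, SEMA3B at 0.25, RELL1 at 0.24 and SNTB2 at 0.22 in the authors' deposited table. To these came PAPSS2, an enzyme of sulfate activation, at 0.20 (SE 0.031, adjusted p = 1.38e-06) and CYP1A1 at 0.16 (SE 0.037, adjusted p = 0.040) in the authors' deposited table. ESR1 at -0.11 (SE 0.03, adjusted p = 0.245), PGR at -0.33 (SE 0.2, adjusted p = 1.000), CXCL12 at -0.17 and MYC at -0.07 were not called in the authors' deposited table. Of the oestrogen-induced list 2 of 42 fell and 0 rose (3 and 1 adjusted over the list alone, median -0.04). Its adjusted p with cameraPR was 0.029, and 0.222 with an inter-gene correlation of 0.05. Of 9 aryl hydrocarbon receptor targets 1 rose, or 3 adjusted over the list alone (median 0.11, adjusted p = 1.61e-03 with cameraPR, 0.157 on ranks).

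In T47D, genes called at 45 min of FULV were nearly all higher than with DMSO, and 14 of the 20 were also called higher with E2, which was compared with the same DMSO samples. The authors' deposited table held 20 called genes of 32240 (0.062%), 19 higher and 1 lower. JUN, a subunit of the AP-1 transcription factor at chromosome 1, 58780788 to 58784327, rose by 1.21 (SE 0.057, adjusted p = 8.71e-97) at an abundance of 61.1 CPM in that table of the authors. The matricellular protein gene CCN1 rose by 0.74 (SE 0.073), AMOTL2 by 0.49 (SE 0.056), KLF6 by 0.47 (SE 0.056), ELF3 by 0.51 (SE 0.075), MYC by 0.53 (SE 0.082, adjusted p = 4.79e-07) and HES1 by 0.41 (SE 0.065) in the authors' deposited table. EGR1 at 0.83, RNF223 at 0.76, RND3 at 0.70, the stress factor gene ATF3 at 0.64, the phosphatase genes DUSP6 at 0.61 and DUSP1 at 0.47, PPP1R15A at 0.38 and DDIT3 at 0.37 rose as well in the authors' deposited table. The remaining increases were RCAN1 at 0.28, RHOB at 0.25, KRT23 at 0.24 and GLUL at 0.19, and the decrease was CAPN7 at -0.24 (SE 0.054, adjusted p = 0.021) in the authors' deposited table. Of 30 immediate early genes 7 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.17, adjusted p = 2.60e-56 with cameraPR), where 0.062% of all genes were called. The oestrogen-induced list shifted upward with 1 of 42 called, or 2 adjusted over the list alone (median 0.05, adjusted p = 1.46e-07 with cameraPR), and the called member was MYC. With E2 the immediate early and oestrogen-induced lists also shifted upward (adjusted p = 6.27e-70 and 5.06e-133 with cameraPR). For each list as a whole, an effect of FULV cannot be told apart from the shared DMSO samples. GREB1 at 0.12 (SE 0.057), PGR at -0.02, CCND1 at 0.05, TFF1 at 0.39 (SE 0.22) and CXCL12 at 0.04 were not called (each adjusted p = 1.000) in the authors' deposited table. The 13 mitochondrial messenger RNAs had a median of -0.26 with 0 called and 0 adjusted over the list alone (adjusted p = 0.020 with cameraPR, 0.072 with a correlation of 0.05), and 0 had an unadjusted p below 0.05. The 12 reference genes had a median of 0.04, again with 0 called and 0 adjusted over the list alone (adjusted p = 0.032, or 0.082 with a correlation of 0.05), and 2 had an unadjusted p below 0.05.

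At 4 h all 31 genes called with FULV in T47D were lower (of 31618 tested, 0.098%) in the authors' deposited table. At an unadjusted p below 0.05, 279 genes were higher and 333 lower in that table of the authors. Its median implied SE at 100 to 200 CPM, 0.068, was larger than the 0.041 to 0.058 of the other 7 tables, and whether a single sample lay behind this could not be looked at. CXCL12, at chromosome 10, 44370165 to 44386493, had a log2 fold change of -1.30 (SE 0.083, adjusted p = 1.66e-50) at an abundance of 170.1 CPM in the authors' deposited table. CISH, a feedback inhibitor of STAT signalling, was at -1.52 (SE 0.12, adjusted p = 3.98e-34) and the mitochondrial phosphatase gene PPM1K at -1.15 (SE 0.085, adjusted p = 1.45e-37) in the authors' deposited table. MYC at -0.84 (SE 0.12, adjusted p = 2.19e-08), ADRA2A at -0.81, FGD3 at -0.80, SEMA6A at -0.66, the bombesin receptor gene GRPR at -0.62, DUSP4 at -0.60 and MYBL1 at -0.59 followed in size in the authors' deposited table. STC2 was at -0.51 (SE 0.075), PGR at -0.35 (SE 0.075, adjusted p = 0.004), GREB1 at -0.30 (SE 0.067, adjusted p = 0.009) and RARA at -0.27 in the authors' deposited table. The remaining 17 called genes, among them SIAH2 at -0.36, IL6ST at -0.30, THBS1 at -0.28 and IGFBP5 at -0.20, had log2 fold changes between -0.52 and -0.20 in the authors' deposited table. ESR1 at -0.14 (SE 0.05), CCND1 at -0.14 (SE 0.051), RET at 0.03, PDZK1 at -0.32 and TFF1 at 0.51 (SE 0.24) were not called (each adjusted p = 1.000) in the authors' deposited table. Of the oestrogen-induced list 9 of 41 fell and 0 rose (11 and 0 adjusted over the list alone, median -0.07, adjusted p = 4.76e-27 with cameraPR). Of 25 cofactors of the oestrogen receptor 2 fell, GREB1 and RARA, or 3 adjusted over the list alone (median -0.03, adjusted p = 3.00e-07 with cameraPR). RARA also stood in the oestrogen-induced list, so the shifts of these 2 lists are not independent. The oestrogen-repressed list was not called (0 of 19 members, 0 higher and 2 lower adjusted over the list alone, 5 at an unadjusted p below 0.05, median 0.04, adjusted p = 0.582). The mitochondrial messenger RNAs had a median of -0.16 with 0 of 13 called and 0 adjusted over the list alone (adjusted p = 0.029 with cameraPR, 0.086 with a correlation of 0.05), and 0 had an unadjusted p below 0.05.

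**Figure D3:**
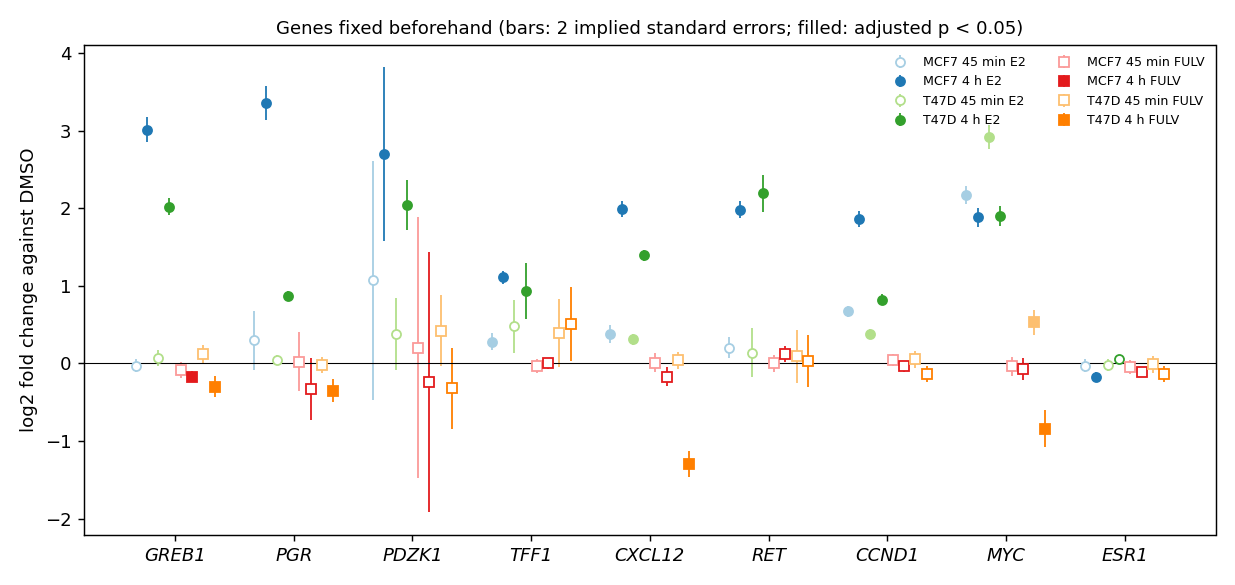
Log2 fold change against DMSO, with bars of 2 implied standard errors either way, of the 9 genes named in every comparison, from the authors' deposited tables, by line, time and treatment, with filled points for called genes. At 4 h of E2 GREB1 reached 3.01 in MCF7 and 2.02 in T47D, and CXCL12 at -1.30 and MYC at -0.84 in T47D were the lowest values with FULV.

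**Figure D4:**
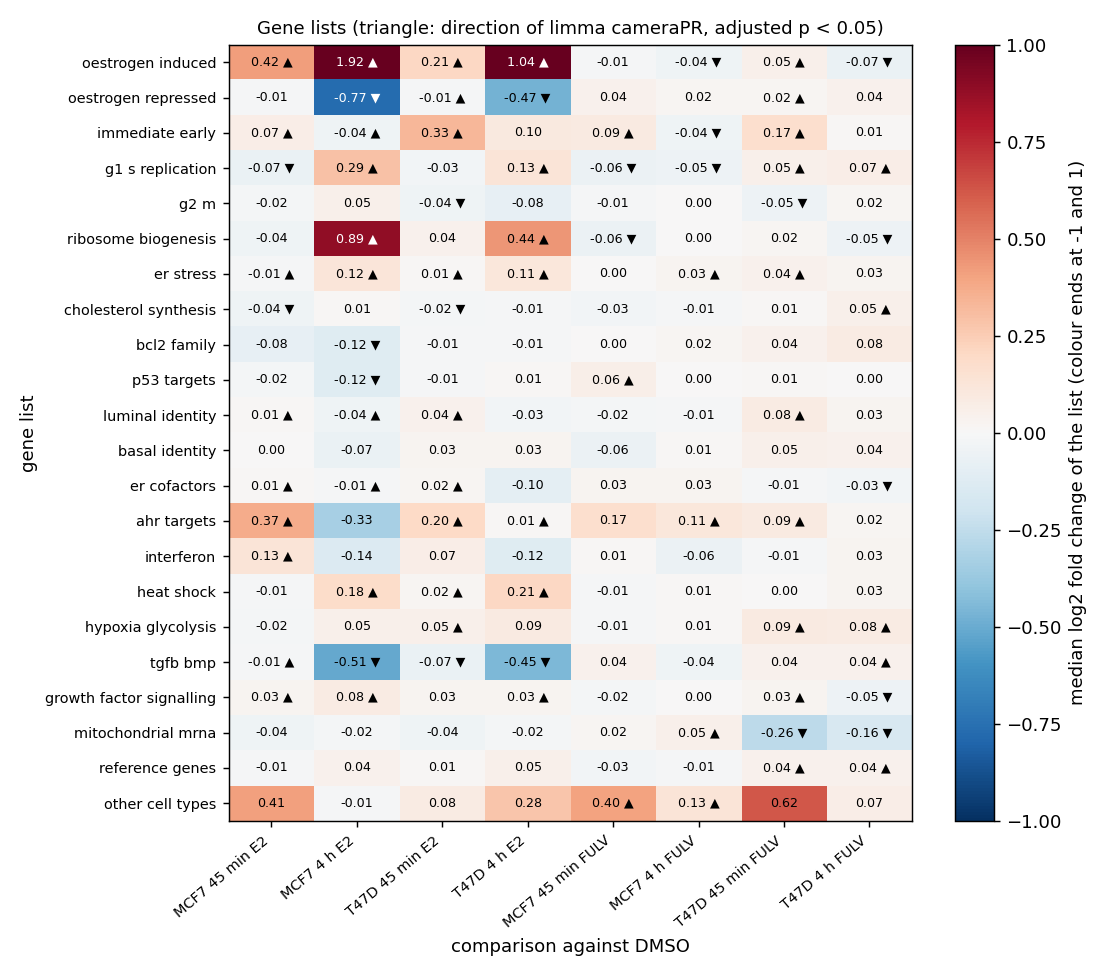
Median log2 fold change of each of the 22 gene lists (vertical) in each of the 8 comparisons (horizontal), as colours and numbers, with triangles for the direction of lists at a cameraPR adjusted p below 0.05. The oestrogen-induced list stood at 1.92 in MCF7 and 1.04 in T47D at 4 h of E2, and at -0.04 and -0.07 with FULV.

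The responses to E2 and to FULV were then set against each other within each line and time. They share the same DMSO samples, so chance alone makes them alike, and the test of the difference, a z from both implied SEs with Benjamini-Hochberg adjustment, ignores that shared part and is conservative. In MCF7 the fold changes differed for 95 of 29913 genes at 45 min and for 2937 of 30713 at 4 h, and in T47D for 83 of 30371 and 1085 of 29761. With a covariance of 0.5 of the geometric mean variance for the shared samples, the counts were 197, 5002, 132 and 2006. GREB1 had the largest difference by z in MCF7 at 4 h, 3.18 (SE 0.09), from 3.01 with E2 and -0.17 with FULV in the authors' deposited table. In T47D at 4 h the largest were STC2 (2.57 against -0.51), the matrix protein gene THBS1 (1.73 against -0.28) and CXCL12 (1.39 against -1.30) in the authors' deposited table. JUN at 45 min in T47D was higher with FULV than with E2, 1.21 against 0.60 in the authors' deposited table, a difference of -0.61 (SE 0.07, adjusted p = 2.62e-13). JUNB went the other way in sign, at -0.71 with E2 and 0.10 with FULV in the authors' deposited table. Of the 31 genes lower with FULV in T47D at 4 h, 29 were called higher with E2 and 0 lower, where independent lists would share 1.64 and 1.24. Of the 20 genes called with FULV in T47D at 45 min, 14 were called higher in both, where independent lists would share 0.104. In MCF7 at 4 h, 8 genes were higher with E2 and lower with FULV, 4 the reverse, 3 higher in both and 1 lower in both, against 0.809, 0.558, 0.719 and 0.628 for independent lists. The samples of DMSO could not be split, so part of any excess in the same direction may come from them.

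Across genes at or above the median abundance, Pearson's r of the E2 and FULV log2 fold changes was 0.554 in MCF7 at 45 min and 0.252 at 4 h, and 0.492 and 0.287 in T47D. The effects of E2 widen the spread of its fold changes and so lower r by themselves, and r is therefore set beside no simulated value. The covariances were 0.0423, 0.0284, 0.0262 and 0.0242, beside 0.0371, 0.0339, 0.0293 and 0.0325 in simulated groups that shared controls and had no effect. Genes are not independent replicates, and these 4 relations carry no p-value. Over genes called with E2 in that abundance range, the slope of the FULV on the E2 fold change was -0.014 in T47D at 4 h, where shared controls alone gave 0.052 with a standard deviation of 0.0102 over 1000 simulations. It was 0.163 in T47D at 45 min (simulated 0.024, standard deviation 0.0221), 0.090 in MCF7 at 45 min (0.057, 0.0234) and 0.033 in MCF7 at 4 h (0.040, 0.0062). The covariances over these called genes were -0.0037, 0.0754, 0.0357 and 0.0187 beside simulated 0.0211, 0.0110, 0.0242 and 0.0210. The simulation treats genes as independent, so its standard deviations are too small. Its slopes for T47D may also be too high, because the FULV fold changes had the larger errors. At 100 to 200 CPM the median implied SE was 0.068 with FULV and 0.041 with E2 at 4 h, and 0.058 and 0.042 at 45 min.

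**Figure D5:**
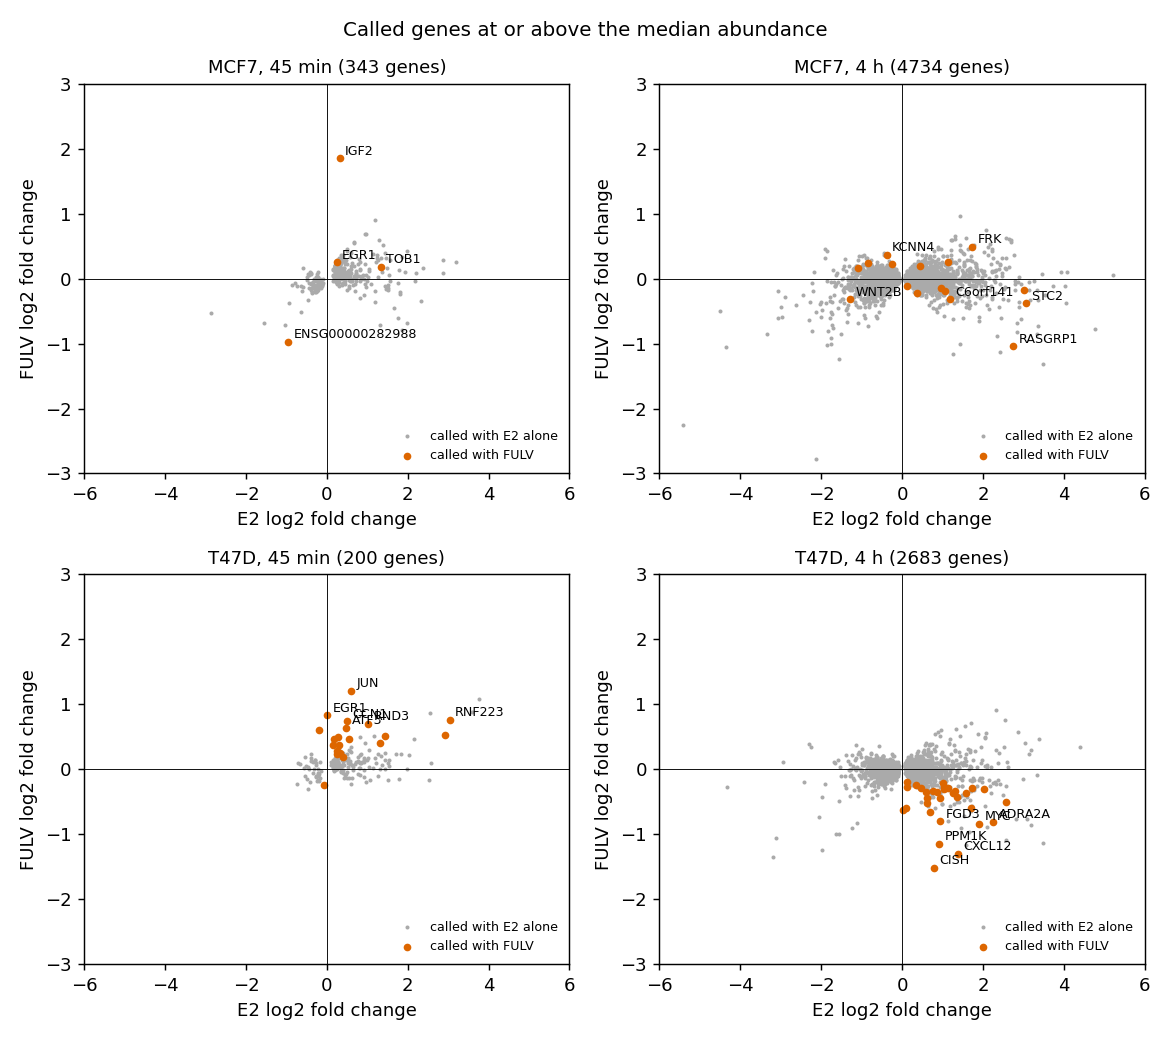
FULV against E2 log2 fold change from the authors' deposited tables for genes called in either comparison at or above the median abundance, in a panel for each line and time, with genes called with FULV in orange and genes called with E2 alone in grey. In T47D the 29 genes called in both at 4 h lie at E2 values above 0 and FULV values below 0, and the 14 genes called in both at 45 min lie above 0 on both axes.

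The E2 response widened and changed between the times. In MCF7 the fold change differed between 4 h and 45 min for 3056 of 28878 genes and in T47D for 1524 of 28948. In the authors' deposited tables GREB1 went from -0.03 to 3.01 in MCF7 and from 0.07 to 2.02 in T47D, and CA12 from 0.09 to 1.62 and the scaffold gene NHERF1 from 0.24 to 1.84 in MCF7. Early increases were gone by 4 h for TOB1 in MCF7 (1.34, then -0.06) and for HES1 (1.32, then -0.19), VASN (2.04, then -0.25) and ELF3 (1.43, then -0.59) in T47D, by the authors' deposited tables. Later decreases included BMF (-0.09, then -1.34) and the myelin protein gene PMP22 (0.03, then -1.05) in MCF7 and ADAMTS15 (0.00, then -1.13) and ENC1 (-0.10, then -1.28) in T47D, by the authors' deposited tables. Genes called higher at both times numbered 172 in MCF7 and 106 in T47D, where independent lists would share 26 and 9.03.

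The lines shared most directions under E2. At 4 h, 1059 genes were called higher and 617 lower in both lines (155 and 91 for independent lists), and 100 went opposite ways. Of these 100, 57 were higher in MCF7 and 43 higher in T47D, fewer than the 117 and 121 for independent lists. At 45 min, 78 were higher and 11 lower in both (1.6 and 0.107), and 2 went opposite ways. The size of the fold change differed between lines for 1755 of 27519 genes at 4 h and 110 of 27583 at 45 min. By the authors' deposited tables RHOBTB1 was at 3.13 in MCF7 and -0.55 in T47D at 4 h, RHOBTB3 at 1.22 and -0.47, CA12 at 1.62 and 0.22, and TSKU at 2.51 and 0.26. In the same tables of the authors IRX2 was at -0.16 in MCF7 and 1.73 in T47D, and the transcription factor gene RUNX1 at 0.04 and 1.32. At 45 min DLX3 was at 1.86 in MCF7 and 0.17 in T47D and XBP1 at 1.00 and 0.26, while ARC was at 0.29 and 3.77 and JUN at -0.24 and 0.60 in the authors' deposited tables.

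The FULV responses differed between the lines for 11 of 27637 genes at 45 min and 4 of 27771 at 4 h, each with the T47D fold change the higher at 45 min and the lower at 4 h. JUN was at -0.02 in MCF7 and 1.21 in T47D at 45 min (adjusted p = 4.11e-58) by the authors' deposited tables and the z of the difference. The 4 genes at 4 h were CXCL12 (-0.17 in MCF7, -1.30 in T47D), CISH (-0.29, -1.52), MYC (-0.07, -0.84) and THBS1 (0.00, -0.28) in the authors' deposited tables. Between 4 h and 45 min the FULV fold change differed for 20 of 28956 genes in T47D, each lower at 4 h, led by CXCL12 (0.04, then -1.30), JUN (1.21, then 0.00) and PPM1K (-0.12, then -1.15) in the authors' deposited tables. In MCF7 it differed for 0 of 29203 genes by the z of the difference after Benjamini-Hochberg adjustment, and for 746 at an unadjusted p below 0.05.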

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

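The tests on shared DMSO samples and on slopes in this part were chosen only after the results they measure were seen, whereas both tests on the immunoglobulin genes and the tests of differences were chosen before.

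Differences between groups under the same treatment drew attention where the z of the difference passed an adjusted p of 0.05, or where genes called in both groups moved in opposite directions. With E2, the fold change differed between 4 h and 45 min for 3056 genes in MCF7 and 1524 in T47D. Of the genes called at both times, 18 in MCF7 and 15 in T47D went opposite ways. In MCF7, 15 were higher early and lower later and 3 the reverse, where independent lists would share 20.2 and 7.93. In T47D there were 15 and 0, against 6.82 and 1.96. Between the times, only the reversals from higher to lower in T47D exceeded the number for independent lists. In both lines BCL3, CYP1B1 and ELF3 were among those that rose early and were lower than with DMSO later. These names and the next were chosen after their values were seen. CDK6 was at 0.25 and then -0.91 in MCF7, and BCL3 at 0.53 and then -0.73 in T47D, in the authors' deposited tables. Between the lines the E2 fold change differed for 110 genes at 45 min and 1755 at 4 h. Opposite directions were seen for 2 genes at 45 min, JUN (-0.24 in MCF7, 0.60 in T47D) and RND1 (0.43 in MCF7, -0.46 in T47D), and for 100 genes at 4 h. At 45 min independent lists would share 0.348 genes higher in MCF7 and lower in T47D, and 0.491 the reverse. At 4 h these numbers were 117 and 121, and fewer genes, 57 and 43, were seen. LRP2 at 4 h was at -1.29 in MCF7 and 1.94 in T47D, and ONECUT2 at 1.83 and -0.39, in the authors' deposited tables. All of these genes with opposite directions also passed the test of the difference. This adds no support, since calls of opposite sign in both groups nearly fix the outcome of that test.

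With FULV, the fold change differed between the times for 20 genes in T47D and between the lines for 11 genes at 45 min and 4 at 4 h. A single gene, 1 in all, was called at both times in T47D with opposite directions. It was MYC, at 0.53 at 45 min and -0.84 at 4 h in the authors' deposited tables (adjusted p of the difference 4.11e-17). No time and no line had samples processed in batches that the labels name, so a batch that coincides with a line or a time cannot be told apart from it.

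The first pattern weighed is that of IGHG1 to IGHG4, called higher with E2 in MCF7 at 45 min from abundances listed at 0. RNA from antibody-producing cells or from another library would also bring light chain genes and JCHAIN, and 1 of these 5 genes had a log2 fold change above 1. The bound set beforehand counted this as evidence against such RNA, but of the 5 only JCHAIN was listed in that table, at 0, and the 4 light chain and 3 heavy chain variable genes it did list, 0 called and 0 at an unadjusted p below 0.05, were also all at 0, so this source stays open. A response to E2 was tested in the other 3 E2 tables, where 5 of the 11 listed values of these genes were called higher, 4 in MCF7 at 4 h and 1 in T47D. Transcription of the region with E2 may therefore be at work, while reads shared among the close copies make the count of genes uncertain, and the abundances listed for them, 0 to 0.2 CPM, do not give the level with E2.

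The second pattern is that all 31 genes called with FULV in T47D at 4 h were lower. DMSO samples that stood high by chance would have lowered both fold changes, yet 29 of these genes were called higher with E2 and 0 lower (1.64 and 1.24 for independent lists). This argues against chance that struck genes regardless of their E2 response as the whole cause. It cannot weigh against DMSO samples that stood high for E2 targets as a group, since targets with large increases would still be called higher with E2. Loss of a residual oestrogen response should also lower E2 targets that FULV did not call, and over those at or above the median abundance the slope was 0.002, beside 0.054 simulated with a standard deviation of 0.0106. The simulated slope may be too high, since the median implied standard error at 100 to 200 CPM was 0.068 with FULV and 0.041 with E2. Those of these targets that rose with E2 had a median FULV log2 fold change of 0.01. The test therefore does not decide whether such a loss contributed. Over the targets of any abundance that FULV did not call the slope was 0.10 (simulated 0.112, standard deviation 0.0368). There 82 genes of lower abundance held 49.4% of the weight, and the simulated data showed the test to be unreliable. Effects of handling or of a medium change could not be tested, nor could a sample that stands apart in this comparison, whose table had the largest median implied standard error of the 8 at 100 to 200 CPM (0.068).

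The third pattern is that 19 of the 20 genes called with FULV in T47D at 45 min were higher. Low DMSO samples would raise E2 and FULV alike, and 14 of the genes were called higher with E2, 5 with the larger change under E2 and 2 (JUN and DUSP6) with the larger change under FULV. Chance in the DMSO samples does not account for the larger change with FULV in those 2 genes, and for the others it cannot be told apart from an effect because both treatments share the same control. A weak oestrogen-like response would raise the slope over genes called with E2 and not with FULV, and it was 0.126 (simulated 0.029, standard deviation 0.0277) at or above the median abundance without the immediate early list, while 0.229 (0.052, 0.0598) at any abundance, with 33.4% of the weight in 8 genes of low abundance, and 0.147 (0.026, 0.0250) with the genes called with FULV kept decide nothing. In the set with the slope of 0.126, 18.1% of the 138 genes that rose with E2 were lower with FULV. Of the 33 that fell with E2, 39.4% were higher with FULV, beside 42% of opposite sign simulated over the set. The likeness thus lay mostly in genes that rose. A weak oestrogen-like response may contribute, but low DMSO samples would shift the slopes in the same direction, and a response to handling of treated cultures was not tested.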

How the results depend on the processing

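The alternatives for the slopes were chosen after the data were seen, and all other alternatives and tests in this part before.

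No paired analysis was possible because the tables hold no values per sample. For the same reason a second count-based test with its own size factors, omission of a low-count filter, another pseudocount and leaving out each replicate were not run, and other splits of the samples could not be drawn. Over the alternatives run, 438 of 623 values kept their direction and their side of the threshold, or stayed within 1.5 times the count. Of the rest, 34 counts moved further, 143 results were no longer past the threshold (142 of them single lists or genes), 7 lists reversed and 1 slope newly passed 2 standard deviations.

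With an absolute log2 fold change of at least 1, the called genes with E2 numbered 65 of 355 and 684 of 4904 in MCF7 at 45 min and 4 h, and 45 of 202 and 323 of 2766 in T47D. With FULV they numbered 1 of 4 and 2 of 17 in MCF7, and 1 of 20 and 3 of 31 in T47D. The fall follows from the setting itself, since most calls were of smaller changes. An adjusted p below 0.01 left 1 of 4 genes for FULV in MCF7 at 45 min and 7 of 11 genes that differed between the lines with FULV at 45 min. The own adjustment, the genes in all 8 tables and those at or above the median abundance left the numbers of called genes within 1.5 times.

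The number of lists called by cameraPR depended on the measure. With the log2 fold change in place of z it fell to 0 from 11 (E2) and 5 (FULV) in MCF7 at 45 min, to 2 from 13 and 0 from 7 at 4 h, to 0 from 12 and 0 from 12 in T47D at 45 min, and to 1 from 9 and 0 from 10 at 4 h. Those left were the oestrogen-induced list at 4 h of E2 in both lines and ribosome biogenesis in MCF7. This setting weighs all genes alike, also the imprecise fold changes of the 9489 to 10288 genes per table listed at 0 CPM. A call lost in it is therefore no evidence that a list did not shift. On ranks the number of lists called was 6 (E2) and 2 (FULV) in MCF7 at 45 min, 7 with E2 in MCF7 at 4 h and 6 with E2 in T47D at 45 min. With a correlation of 0.05 it was 3 and 1 with FULV in MCF7 at 45 min and 4 h, and 7 and 6 in T47D. Over genes at or above the median abundance it was 4 with FULV in MCF7 at 4 h. Lists that reversed on ranks, none past the threshold there, were luminal identity (adjusted p = 0.950 in MCF7 at 45 min of E2, 0.716 at 4 h), TGF-beta and BMP (0.950 in MCF7 at 45 min), immediate early (0.840 in MCF7 at 4 h), cofactors of the receptor (0.997 in MCF7 at 4 h) and oestrogen-repressed genes (0.818 in T47D at 45 min). Aryl hydrocarbon receptor targets reversed with the log2 fold change (0.931 in T47D at 4 h of E2). The cause was not tested.

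A difference of at least 0.5 left 61 of 95 and 1361 of 2937 genes that differed between E2 and FULV in MCF7, and 596 of 1085 in T47D at 4 h. With a covariance of 0.5 of the geometric mean variance they numbered 197 and 5002 in MCF7 and 132 (from 83) and 2006 in T47D, since the error of the difference is then smaller. Over genes of any abundance the slope of FULV on E2 was 0.247 in MCF7 at 45 min (0.090 before, now beyond 2 standard deviations) and 0.090 in T47D at 4 h (-0.014 before, now within 2). On simulated data this setting was unreliable. Without genes called with FULV the slopes were 0.086 and 0.036 in MCF7 and 0.134 and 0.002 in T47D, and without the immediate early list 0.095, 0.034, 0.147 and -0.012, each on its former side.

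Depth per sample is unknown, so what it limits was read from the implied standard error, which at 1 to 2 CPM had a median between 0.31 and 0.37.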

Other observations

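All tests in this part, those of the gene lists, were chosen before the data were examined. The genes near the immunoglobulin region were chosen after their values were seen. Counts of called list members are over all genes tested, then adjusted over the list alone, and p-values of lists are adjusted values of cameraPR with its preset correlation.

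In MCF7 at 45 min of E2, luminal identity genes shifted upward (3 of 21 higher and 1 lower, 4 and 2 adjusted over the list alone, adjusted p = 2.71e-08, 0.950 on ranks). Cofactors of the receptor had 3 of 25 higher and 3 lower (5 and 3 adjusted over the list alone, median 0.01, adjusted p = 0.004 upward, 0.656 on ranks). TGF-beta and BMP genes had 3 of 14 higher and 1 lower (3 and 2 adjusted over the list alone, adjusted p = 0.004 upward). Their median was -0.01, and on ranks their direction turned and they were not called (adjusted p = 0.950). Endoplasmic reticulum stress genes had 1 of 18 higher and 1 lower in both ways of adjusting, and the test gave a shift upward (adjusted p = 4.76e-04) beside a median of -0.01 and a mean of 0.11, and was not called on ranks (adjusted p = 0.969). G1/S and replication genes shifted downward (median -0.07, 1 of 31 lower, adjusted p = 1.06e-04), with MCM2 at -0.22 in the authors' deposited table. This list also shifted downward with FULV, compared with the same DMSO samples (median -0.06, adjusted p = 9.73e-04). Cholesterol synthesis (adjusted p = 0.011), interferon (adjusted p = 0.032) and growth factor signalling (adjusted p = 0.032) were past the threshold but not with a correlation of 0.05 (0.072, 0.120 and 0.120). Of 20 interferon genes 0 were called and 3 had an unadjusted p below 0.05. Markers of other cell types had 0 of 18 genes called and 0 at an unadjusted p below 0.05 (adjusted p = 0.724).

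In MCF7 at 4 h of E2, immediate early genes (9 of 30 higher and 8 lower, adjusted p = 1.23e-04), luminal identity genes (8 and 8 of 21, adjusted p = 2.58e-03) and cofactors (11 and 8 of 25, adjusted p = 3.44e-04) went both ways. Their tests gave shifts upward beside medians of -0.04, -0.04 and -0.01 and means of 0.18, 0.07 and 0.41, and on ranks none was called. Lists not past the threshold were G2/M (adjusted p = 0.781), cholesterol synthesis (adjusted p = 0.797), aryl hydrocarbon receptor targets (2 of 9 higher and 5 lower, adjusted p = 0.781), interferon (adjusted p = 0.062), hypoxia and glycolysis (adjusted p = 0.345), mitochondrial messenger RNAs (adjusted p = 0.607), reference genes (adjusted p = 0.093) and markers of other cell types (1 of 15 higher, also adjusted over the list alone, adjusted p = 0.952). The marker that rose was VWF, at 1.71 (adjusted p = 4.07e-10) at an abundance of 1.2 CPM in the authors' deposited table. On ranks the interferon list was called (adjusted p = 1.00e-03), with 0 of 20 members higher, 4 lower and a median of -0.14.

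In T47D at 45 min of E2, aryl hydrocarbon receptor targets rose (3 of 9, also adjusted over the list alone, adjusted p = 1.84e-24, 0.063 on ranks). Cofactors had 3 of 25 higher and 3 lower (adjusted p = 1.73e-05, 0.817 on ranks). Hypoxia and glycolysis genes shifted upward (1 of 17 higher, adjusted p = 1.49e-03), with ADM at 1.27 in the authors' deposited table. G2/M (median -0.04, adjusted p = 0.009), endoplasmic reticulum stress (adjusted p = 0.010), cholesterol synthesis (median -0.02, adjusted p = 0.016) and heat shock (adjusted p = 0.018) were past the threshold but not with a correlation of 0.05 (0.057, 0.054, 0.079 and 0.054). At 4 h of E2, aryl hydrocarbon receptor targets had 2 of 9 higher and 2 lower, SLC7A5 at 0.98 and CYP1A1 at -1.28 among them in the authors' deposited table. The test gave a shift upward (adjusted p = 1.75e-03) beside a mean of -0.17, and the adjusted p was 0.962 on ranks. Cofactors had 6 of 25 higher and 12 lower (adjusted p = 0.342), and immediate early genes 5 of 30 higher and 7 lower (adjusted p = 0.053). Interferon genes had 0 of 20 higher and 2 lower (median -0.12, adjusted p = 0.058, 0.004 on ranks).

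In MCF7 with FULV, p53 targets at 45 min (median 0.06, adjusted p = 0.019) and, at 4 h, immediate early genes (-0.04, adjusted p = 0.029), G1/S genes (-0.05, adjusted p = 0.010), endoplasmic reticulum stress (0.03, adjusted p = 0.029), mitochondrial messenger RNAs (0.05, adjusted p = 0.010) and markers of other cell types (0.13, adjusted p = 0.030) were past the threshold. None was with a correlation of 0.05. In each of these lists 0 genes were called, also adjusted over the list alone, and 3, 1, 2, 1, 0 and 3 had an unadjusted p below 0.05.

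In T47D at 45 min of FULV, luminal identity genes (1 of 21 higher, 4 adjusted over the list alone, median 0.08, adjusted p = 3.87e-08), endoplasmic reticulum stress (1 of 18, 2 adjusted over the list alone, adjusted p = 2.27e-04), G1/S genes (median 0.05, adjusted p = 1.94e-03), aryl hydrocarbon receptor targets (median 0.09, adjusted p = 1.94e-03) and hypoxia and glycolysis (median 0.09, adjusted p = 7.01e-06) shifted upward, also with a correlation of 0.05. Of the last 3 lists 0 members were called over all genes, 1, 0 and 0 adjusted over the list alone, and 5, 2 and 4 had an unadjusted p below 0.05. These medians stood beside 0.04 for the reference genes and -0.26 for the mitochondrial messenger RNAs. With E2, compared with the same DMSO samples, the luminal, endoplasmic reticulum stress, aryl hydrocarbon receptor and hypoxia lists also shifted upward (adjusted p = 1.22e-25, 0.010, 1.84e-24 and 1.49e-03). For these an effect of FULV cannot be told apart from the shared samples. The G1/S list was not called with E2 (median -0.03, adjusted p = 0.146). Oestrogen-repressed genes (upward, adjusted p = 0.013), G2/M genes (downward, adjusted p = 0.013) and growth factor signalling (upward, adjusted p = 0.045) were past the threshold with FULV only with the preset correlation. At 4 h of FULV, G1/S genes (median 0.07, adjusted p = 2.88e-05) and cholesterol synthesis (0.05, adjusted p = 2.74e-03) shifted upward, and ribosome biogenesis (-0.05, adjusted p = 2.74e-03) and growth factor signalling (-0.05, adjusted p = 0.005) downward. With a correlation of 0.05 all 4 lists stayed below the threshold, the last pair only just (both 0.050 after rounding), but growth factor signalling was not called on ranks (adjusted p = 0.162). Of these 4 lists 0, 0, 0 and 1 members were called over all genes, 0, 0, 0 and 2 adjusted over the list alone, and 1, 2, 3 and 6 had an unadjusted p below 0.05. Their medians stood beside 0.04 for the reference genes and -0.16 for the mitochondrial messenger RNAs. The G1/S list also shifted upward with 4 h of E2, compared with the same DMSO samples (median 0.13, adjusted p = 1.24e-04). An effect of FULV on that list cannot be told apart from the shared samples. Hypoxia and glycolysis (0.08, adjusted p = 0.011), TGF-beta and BMP genes (0.04, adjusted p = 0.043) and reference genes (0.04, adjusted p = 0.025) shifted upward but were not called with a correlation of 0.05. Of these 0 members were called, also adjusted over the list alone, and 1, 0 and 0 had an unadjusted p below 0.05. Basal identity was called in no comparison, with adjusted p between 0.535 and 0.931.

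Near the immunoglobulin heavy chain constant genes, FAM30A, a long non-coding RNA listed at 0, was called higher with E2 in MCF7 at 4 h (adjusted p = 7.41e-06 in the authors' deposited table). On the other side of the region, CRIP2 at -0.35 (adjusted p = 6.31e-23) and TEDC1 at -0.48 (adjusted p = 3.47e-12) fell in the same table of the authors. CRIP2 was also lower in T47D at 4 h, at -0.14 (adjusted p = 0.005 in the authors' deposited table). Other neighbours were not called in MCF7 at 4 h, among them TMEM121, CRIP1, MTA1, PACS2 and BRF1. Their adjusted p in the authors' deposited table was 0.078, 0.068, 0.501, 0.457 and 0.631. Since 15.2% of all genes were called there, the called neighbours do not by themselves show a response of the wider region.

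Among genes of at least 1 CPM, 2.53% had an unadjusted p below 0.05 with FULV in T47D at 4 h in the authors' deposited table, and between 4.46% and 5.64% in the other 3 FULV tables. A sample that stands apart in that comparison could not be looked for without values per sample.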
